A study of Arabidopsis thaliana with 9 samples.

How the data were processed

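Whole roots of Col-0, cap-h2-2 and crwn1/4 plants were each represented by 3 arrays, 9 in all, and the group of each array was taken from its label. Per the labels' protocols, plants grew on gellan gum medium without treatment, RNA was taken with a plant RNA reagent, and labelled RNA in 1 colour (Cy3) was hybridised to an array of custom design. Per the file headers, the deposited intensity values were extracted from the scans with Agilent Feature Extraction 10.7.3.1, which subtracted the background, removed trends over the slide and set substitute values for spots at background, without normalization between arrays. The deposited files also hold the mean spot intensity and the local background intensity as scanned, and marks for spots well above background, saturated or out of the ordinary. The deposited value table holds log2 values that are near equal in distribution across arrays, and the submitters' processing notes name RMA and limma without versions or order of use. Of its 36975 entries 36968 matched a probe. Within an array its values correlated over probes with the log2 of the mean spot intensity as scanned, with r of 0.997 to 0.999. No correlation with the background-subtracted and scaled values tested here was computed.

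Spots marked as outliers were left out and the spots of each probe were averaged, which gave 52586 probes from 53459 spots, 97 of the probes with 10 spots. The log2 of the processed intensity was taken and the 75th percentile of each array subtracted. For a gene with several probes the brightest was used, and probes without a gene name were kept as features of their own. A feature was tested when it was well above background on all arrays of at least 1 group, which kept 36420 of 52489 features, 24489 of them gene loci, and left out 16069. Of the 32781 loci on the array 32316 matched the reference gene table, which is of the TAIR10.1 assembly, and 465 did not. The build named in the file headers is another one, so the table served only for names, gene classes and the order of neighbours, and no coordinates are given. A planned comparison of changed genes by their distance to the centromere was not run for this reason. The probe sequence of 282 loci was shared with another locus, and 222 of these were tested.

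All 9 arrays were fitted in 1 linear model of group means with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (6 residual and 1.92 prior degrees of freedom), and each mutant was compared with Col-0 and crwn1/4 with cap-h2-2. The p-values were adjusted by the Benjamini-Hochberg method over all tested features, and an adjusted p under 0.05 was called a change. The 23 gene lists hold 409 genes, 378 of them measured, and were compared with the other genes by camera with a preset correlation of 0.01, with an estimated correlation as an alternative. By fry it was tested whether the genes of a list moved one way on balance, without regard to the other genes. Both were adjusted over the lists of a comparison. Lists needed at least 5 measured members. The share of pseudogenes among changed loci was compared by Fisher's exact test. Among lists that did not pass, mean and median differed in sign for jasmonate and copper in cap-h2-2, for DNA damage response, nuclear lamina and flavonoid synthesis in crwn1/4, and for nuclear lamina, DNA replication and clock between the mutants. The camera test was upward beside a median below 0 for nuclear lamina and endodermis in cap-h2-2 and for DNA damage response in crwn1/4, and downward beside a median above 0 for nuclear lamina in crwn1/4 and for nuclear lamina and DNA replication between the mutants.

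Genes to be named were chosen by a rule. For each comparison with Col-0 these were up to 12 genes with the highest and 12 with the lowest log2 fold change among those with an adjusted p under 0.05 and no overlap between the groups' values, and up to 6 and 6 for the comparison of the mutants. CAP-H2, CRWN1 and CRWN4 were always chosen, as were up to 4 passing members of each list with the largest change, or up to 2 with the smallest p where none passed. The text gives only some of the chosen genes. It also gives some that the rule did not choose, such as TSO2 in cap-h2-2 and XRI1 between the mutants. The tests of named genes counted below are those of the genes the rule chose, without CAP-H2, CRWN1 and CRWN4. Features without a gene name were counted and not named. The rule, the lists, the comparisons and most alternatives were set before the data were examined. The alternatives were normexp background correction with an offset of 50, quantile normalization, both together, median centring, the deposited value table, no filter on dim features, only features well above background on all 9 arrays, the mean of a gene's probes, only the 6 arrays compared, replicate number or slide as a block, an intensity trend with a robust prior, a fold threshold of log2 1, and each array left out in turn. Cyclic loess normalization, array weights, the use of only probes named for a locus, and the condensin and nuclear lamina lists without the genes the lines are named after were added after the data had been seen.

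The procedure was tested on simulated data with known changes. In the simulated cap-h2-2 comparison 14.9, 58.2 and 93.9% of genes changed by log2 0.5, 1 and 2 were recovered, with 5.13% of the calls false, in the simulated crwn1/4 comparison 14.9, 73.1 and 87.9% with 3.31% false, and in the simulated comparison of the mutants 10.4, 76.1 and 90.9% with 9.23% false. The 36396 simulated genes took their levels and spread from the real ones, with independent normal noise. In each comparison 66 or 67 genes were changed by each size, and the simulation was not repeated. Far more features were called in the real comparisons, so the shares recovered and false need not hold for them.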

Results

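Gene expression was measured in whole roots of 2-week-old Arabidopsis thaliana plants of 3 genotypes, on 9 arrays of 1 colour, 3 arrays per genotype. Col-0 is the wild-type accession. The line cap-h2-2 is named after CAP-H2, a subunit of the condensin II complex that folds chromosomes, and crwn1/4 after CRWN1 and CRWN4, which are plant proteins of the nuclear lamina. The title given to the series concerns the placing of centromeres in the nucleus. The arrays allow the transcripts of the roots to be compared between each mutant and Col-0 and between both mutants. The percentage of spots well above background was 73.6 ± 1.74 in Col-0, 65.0 ± 0.73 in cap-h2-2 and 69.8 ± 0.87 in crwn1/4 (mean ± SD, n = 3 arrays), so that fewer spots stood out from background in both mutants than in Col-0. No spot was saturated, 22 to 39 spots per array were marked as outliers and left out, and the 75th percentile of the signal ran from 310 to 405. Arrays of 1 genotype correlated over features with r of 0.986 to 0.992, and arrays of different genotypes with r of 0.972 to 0.986. The number of arrays limits the precision of every value below. No label says that replicates came from separate cultures, so the p-values measure only the spread between these samples.

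The transcripts of the mutated genes were lower in the lines named after them. CAP-H2 (HEB2 in the reference table, AT3G16730) was at least 4.31-fold lower in cap-h2-2 than in Col-0 (limma adjusted p = 0.000107, n = 3 arrays per group) and was not well above background on any cap-h2-2 array. CRWN1 (LINC1, AT1G67230) was at least 145-fold lower in crwn1/4 (adjusted p = 5.66e-09) and was likewise not well above background on any array of that line. CRWN4 (LINC4, AT5G65770) changed by −4.60 ± 0.34 on the log2 scale (SE; adjusted p = 0.000765), with 1 of the 3 crwn1/4 arrays well above background. The sizes depend on how background is treated: with normexp background correction CAP-H2 changed by −1.02, CRWN1 by −5.43 and CRWN4 by −2.21, so the bounds hold only for the processed signal used here. In the other mutant, CAP-H2 differed from Col-0 by −0.06 (adjusted p = 0.827), CRWN1 by −0.15 (adjusted p = 0.320) and CRWN4 by −0.02 (adjusted p = 0.981). ATBCAT-5, a branched-chain aminotransferase gene that lies next to CRWN4 in the gene order, was at least 15.1-fold lower in crwn1/4 (adjusted p = 6.39e-07) and differed by −0.08 in cap-h2-2 (adjusted p = 0.671). The places of the probes relative to the mutations are not given in the sources used here, so a lower signal may reflect less transcript or a transcript without the probed part. Here and below, "at least" marks a gene that was not well above background on any array of one group. Its bound is the mean of the bright group over a mean that takes, on each dim array, the higher of the gene's own signal and the lowest signal well above background. Where only some arrays of a group were well above background their number is given, and the size of the change is then no more than approximate, as it rests in part on signals near background.

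**Figure D1:**
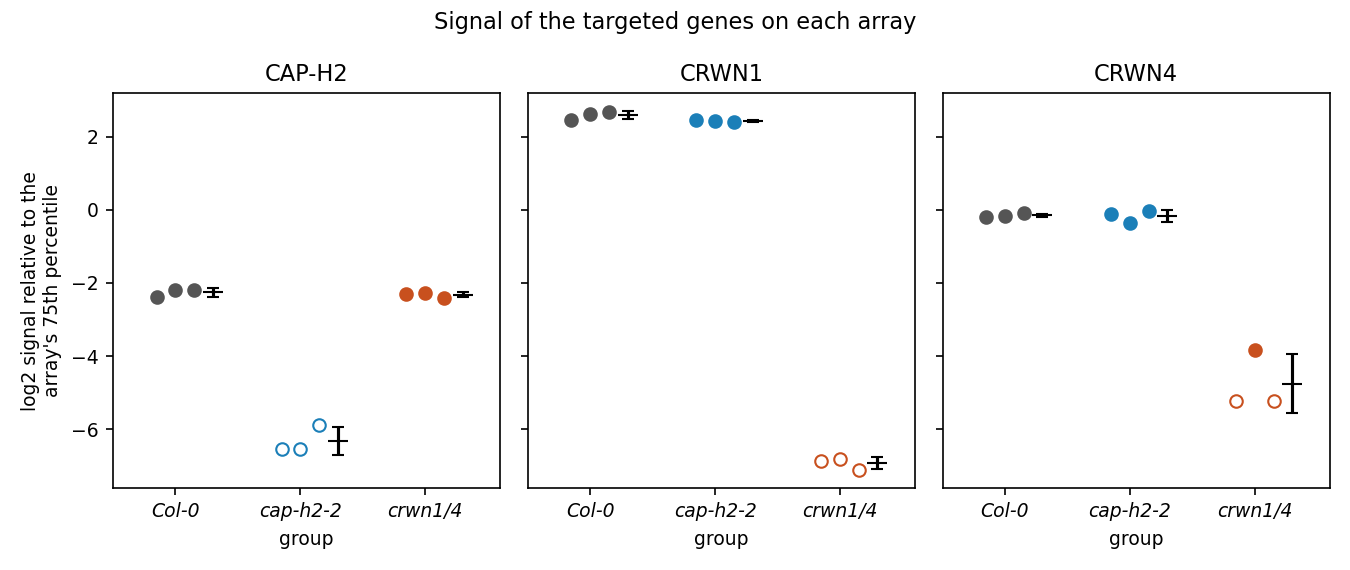
Signal of CAP-H2, CRWN1 and CRWN4 on each array, as log2 relative to the 75th percentile of the array (vertical axis), for the 3 arrays of Col-0, cap-h2-2 and crwn1/4. Filled points are well above background, open points are not, and the black marks give the mean ± SD. CAP-H2 averaged −2.26 in Col-0 and −6.32 in cap-h2-2.

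Comparison of cap-h2-2 with Col-0 asks what the roots express differently when CAP-H2 is disrupted. Regulators that act after DNA damage were higher: the cyclin-dependent kinase inhibitor genes SMR7 (AT3G27630) and SMR5 (AT1G07500) rose by 2.01 ± 0.11 and 1.04 ± 0.14 on the log2 scale (SE, n = 3; limma adjusted p = 0.000441 and 0.0101). NAC044, a transcription factor gene that takes part in cell cycle arrest after damage, rose by 1.77 ± 0.07 (adjusted p = 0.000107). PRX52, a class III peroxidase gene linked to lignin formation, was at least 9.07-fold higher (adjusted p = 1.84e-05), and the ABC transporter gene ABCA10 was at least 5.63-fold higher (adjusted p = 0.00267). CYP71A12, which encodes an enzyme on the path from tryptophan to defence compounds, changed by −4.36 ± 0.46 (adjusted p = 0.00564), and GLIP1, a secreted lipase gene of pathogen defence, by −3.97 ± 0.46 (adjusted p = 0.00725).

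Over all features, 2397 of 36420 differed between cap-h2-2 and Col-0 (limma, Benjamini-Hochberg adjusted p under 0.05), 1328 higher and 1069 lower, and 10457 had an unadjusted p under 0.05. Of the 2397, 113 were at least 2-fold higher and 260 at least 2-fold lower, a balance that depended on the scaling and on the filter. It was 163 and 94 with quantile normalization, 179 and 120 with cyclic loess, 212 and 190 with median centring and 29 and 44 with normexp background correction. With the main scaling it was 84 and 81 for only features well above background on all 9 arrays, and 91 and 213 without a filter on dim features. Leaving out 1 array gave 67 to 139 higher and 100 to 264 lower. Among the genes with the largest increase were the defensin gene PDF1.4 (3.48 ± 0.45, adjusted p = 0.00972, 1 of 3 Col-0 arrays well above background), AT5G60250 (3.57 ± 0.42, adjusted p = 0.00721, 2 of 3 Col-0 arrays) and AT5G52390 (2.51 ± 0.20, adjusted p = 0.00196). RTFL1, which encodes a small peptide of the ROTUNDIFOLIA family, was at least 3.58-fold higher (adjusted p = 0.00983). The lowest was AT2G01422, annotated as a non-coding RNA, at −7.15 ± 0.46 (adjusted p = 0.000781). AT5G38910 was at least 26.1-fold lower (adjusted p = 0.0108) and AT5G34830 at least 3.30-fold lower (adjusted p = 0.000539). CYP82C2, a cytochrome P450 gene of indole defence compounds, fell by 4.33 ± 0.71 (adjusted p = 0.0191). In Col-0 replicate 3 several of these lay apart from the other Col-0 arrays: AT5G38910 read −2.16 there against 1.63 and 1.54, CYP71A12 0.62 against 2.43 and 2.47, and GLIP1 0.80 against 2.51 and 2.66.

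The DNA damage response list moved most clearly among the 23 gene lists. Of its 23 measured members 9 rose, 0 fell and 14 did not pass, and 11 rose when adjusted over the list alone. Besides SMR7, NAC044 and SMR5, the repair protein gene GMI1 rose by 1.08 ± 0.17 (adjusted p = 0.0165) and TSO2, a ribonucleotide reductase gene, by 0.61 ± 0.08 (adjusted p = 0.00983). The list's median was 0.36 (camera adjusted p = 8.34e-06, and adjusted p = 0.570 with an estimated correlation). Flavonoid synthesis genes were lower, and of 14 members 0 rose, 5 fell and 9 did not pass, while 6 fell when adjusted over the list alone. Their median was −0.32 (camera adjusted p = 0.00104, and adjusted p = 0.570 with an estimated correlation). The enzyme genes F3'H (TT7) and CHI (TT5) fell by 0.72 ± 0.10 and 0.63 ± 0.09 (adjusted p = 0.0113 and 0.0122). Heat shock genes had a median of 0.29 (camera adjusted p = 0.00104, and adjusted p = 0.570 with an estimated correlation). Of 15 members 2 rose, 0 fell and 13 did not pass, with 5 higher when adjusted over the list alone. The small heat shock protein gene HSP17.6B (AT2G29500) rose by 0.79 ± 0.08 (adjusted p = 0.00451).

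Salicylic acid and systemic immunity genes had a median of 0.23 (camera adjusted p = 0.00348, and adjusted p = 0.616 with an estimated correlation). Of 24 measured members 4 rose, 0 fell and 20 did not pass, while 8 rose and 3 fell when adjusted over the list alone. PR1, PR2, PR5, SARD1 and WRKY38 were not measured. AZI1, a lipid transfer protein gene of systemic priming, rose by 1.37 ± 0.10 (adjusted p = 0.00179). Without Col-0 replicate 3 the list no longer passed (adjusted p = 0.0797). DIR1, a gene of systemic acquired resistance outside the list, went the other way in cap-h2-2, by −4.14 ± 0.80 (limma adjusted p = 0.0297, 1 of 3 cap-h2-2 arrays well above background). Core histone genes had a median of −0.29 (camera adjusted p = 0.0241, and adjusted p = 0.616 with an estimated correlation). Of 13 members 0 rose, 2 fell and 11 did not pass, and 8 fell when adjusted over the list alone, with HTB1 at −0.41 ± 0.08 (adjusted p = 0.0310). Condensin subunit genes had a median of −0.18 (camera adjusted p = 0.0450, and adjusted p = 0.623 with an estimated correlation). Of 9 members CAP-H2 itself and CAP-H (EMB2795; −0.38 ± 0.08, adjusted p = 0.0371) fell, 0 rose and 7 did not pass, the same counts as when adjusted over the list alone. This call rested on CAP-H2, the gene the line is named after: without it, an alternative added after seeing the data, the 8 others had a median of −0.16 and did not pass (camera adjusted p = 0.285, adjusted p = 0.763 with an estimated correlation, fry adjusted p = 0.216). Mitotic cell cycle genes had a median of −0.14 (camera adjusted p = 0.0450, and adjusted p = 0.817 with an estimated correlation). Of its 27 members 0 passed alone by either adjustment. With median centring this median turned to 0.02, where that of all features was 0.09. Xylem markers had a median of 0.13 (camera adjusted p = 0.0450, and adjusted p = 0.623 with an estimated correlation). Of 11 members 0 passed by either adjustment, VND6 (NAC101) at 0.30 ± 0.14 (adjusted p = 0.202). By fry the mitotic and xylem lists did not pass (adjusted p = 0.229 and 0.255). The xylem call held in only 5 of 16 alternatives other than leave-outs, in a range of 0.0328 to 0.623. It was lost, among others, with normexp background correction (adjusted p = 0.0795), quantile normalization (0.127), median centring (0.0778), the deposited value table (0.157) and cyclic loess (0.132). The condensin call with CAP-H2 held in 11 of the 16 and was lost with median centring (median −0.02, adjusted p = 0.138), with only features well above background on all arrays, which leaves out CAP-H2 (0.166), with only the 6 arrays compared (0.0609) and with the replicate block (0.0650), in a range of 0.00577 to 0.623. The mitotic call held in 12 and the core histone call in 14, and median centring lost both (adjusted p = 0.450 and 0.231, in ranges of 0.00248 to 0.817 and 0.000154 to 0.616). The core histone call was lost without Col-0 replicate 2 (adjusted p = 0.0797) and cap-h2-2 replicate 2 (adjusted p = 0.0693). The xylem call was lost without Col-0 replicate 1 (adjusted p = 0.298) and cap-h2-2 replicate 1 (adjusted p = 0.220). The condensin and mitotic calls were each lost without Col-0 replicate 2 (adjusted p = 0.194 and 0.364), Col-0 replicate 3 (0.144 and 0.193) and cap-h2-2 replicate 2 (0.142 and 0.167). They were also lost without crwn1/4 replicate 1 (0.0580 and 0.0638) and crwn1/4 replicate 2 (0.0627 and 0.0608).

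The other 15 lists did not pass in cap-h2-2, though single members changed. Of 22 iron deficiency genes 1 rose and 3 fell (camera adjusted p = 0.392). S8H (AT3G12900), whose enzyme makes the iron-mobilising coumarin fraxetin, changed by −3.31 ± 0.28 (adjusted p = 0.00267) and the root iron transporter gene IRT1 by −1.04 ± 0.19 (adjusted p = 0.0253). Abscisic acid and water stress genes numbered 0 rising and 3 falling of 13 (camera adjusted p = 0.117), with KIN1 at −1.13 ± 0.10 (adjusted p = 0.00267). This list passed in 2 of 16 alternatives other than leave-outs, normexp background correction (adjusted p = 0.0213) and the deposited value table (0.0169), in a range of 0.0169 to 0.623. By fry the iron and abscisic acid lists both passed (adjusted p = 0.0223 each). In the clock list 1 rose and 2 fell of 16 (camera adjusted p = 0.953), among them CCA1, a morning-expressed oscillator gene, at −0.53 ± 0.07 (adjusted p = 0.0108). The photosynthesis list had 0 rising and 1 falling of 20 (camera adjusted p = 0.803), the antenna protein gene LHCB1.2 (CAB3) at −2.25 ± 0.47 (adjusted p = 0.0351). Jasmonate genes had 1 rising and 0 falling of 16 (camera adjusted p = 0.298), the synthesis gene AOC2 at 1.50 ± 0.14 (adjusted p = 0.00374). Boron transport had 1 rising and 1 falling of 6 (camera adjusted p = 0.622) and phosphate starvation 1 rising and 0 falling of 17 (camera adjusted p = 0.0841). Root hair (16 members), endodermis (23) and root tip (9) markers had 0 rising and 1 falling each (camera adjusted p = 0.285, 0.953 and 0.719). The root hair list passed, with a median below 0, in 5 of 16 alternatives other than leave-outs: normexp background correction (adjusted p = 0.0244), quantile normalization (0.0206), both together (0.0125), the deposited value table (0.0153) and cyclic loess (0.0111), in a range of 0.0111 to 0.863. It passed also without Col-0 replicate 3 (adjusted p = 0.00682), and phosphate starvation did without cap-h2-2 replicate 1 (0.0467). In the nuclear lamina (19), DNA replication (20), DNA methylation (17), copper (18) and low oxygen (10) lists 0 members passed (camera adjusted p = 0.631, 0.723, 0.852, 0.285 and 0.815).

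Of the 58 tests of named genes that passed in cap-h2-2, the 25 with an adjusted p of 0.0113 or less also passed in each of the 9 fits with 1 array left out. The 33 with 0.0122 or more were lost in at least 1. The count of 2397 fell to 478, 598 and 509 without cap-h2-2 replicates 1, 2 and 3, to 1239 and 1095 without Col-0 replicates 2 and 3 and to 1466 without crwn1/4 replicate 1. The split of 1328 higher and 1069 lower became 1258 and 534 with normexp background correction and 1167 and 477 with quantile normalization. It was 2066 and 503 with median centring and 1529 and 766 with the deposited value table.

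**Figure D2:**
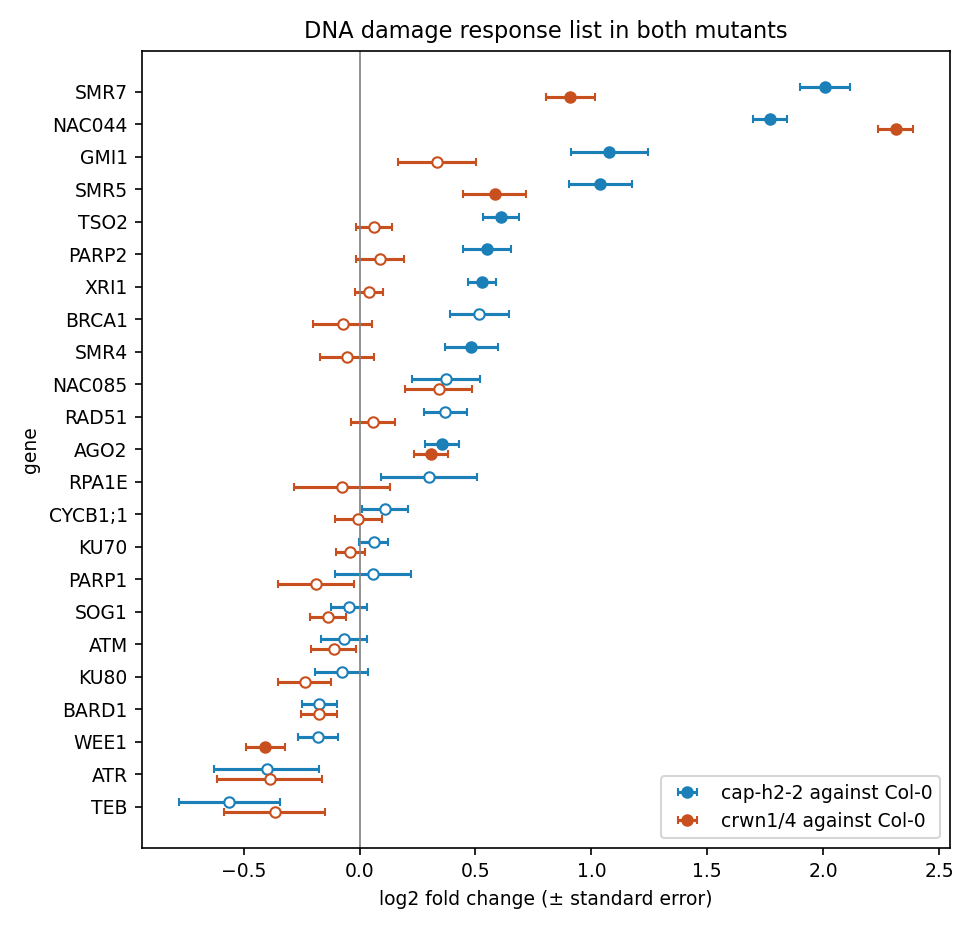
Log2 fold change against Col-0 (horizontal axis) of the 23 measured genes of the DNA damage response list (vertical axis) in cap-h2-2 (blue) and crwn1/4 (orange), with bars of ± 1 standard error from 3 arrays per group. Filled points have an adjusted p under 0.05. SMR7 stood at 2.01 in cap-h2-2 and 0.91 in crwn1/4, and NAC044 at 1.77 and 2.31.

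Comparison of crwn1/4 with Col-0 asks the same of the disruption of CRWN1 and CRWN4. COR47, a dehydrin gene induced by cold and water stress, rose by 2.23 ± 0.08 on the log2 scale (SE, n = 3; limma adjusted p = 2.52e-05). PDC1 (AT4G33070), the pyruvate decarboxylase gene of alcoholic fermentation, rose by 1.35 ± 0.13 (adjusted p = 0.00226), and ERF71, a transcription factor gene of the low oxygen response, was at least 5.03-fold higher (adjusted p = 0.00206). PSAF, a gene of photosystem I, rose by 0.85 ± 0.16 (adjusted p = 0.0232). NAC044 rose by 2.31 ± 0.07 (adjusted p = 1.80e-05). Among the genes that fell were AGL95, a MADS-box gene, at least 3.16-fold lower (adjusted p = 0.000139), and LBD26, a LATERAL ORGAN BOUNDARIES domain gene, at −2.50 ± 0.09 (adjusted p = 2.52e-05).

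Over all features, 3156 of 36420 differed, 1651 higher and 1505 lower (limma adjusted p under 0.05), and 11269 had an unadjusted p under 0.05. Of the 3156, 189 were at least 2-fold higher and 292 at least 2-fold lower, which turned to 264 and 161 with quantile normalization, 274 and 122 with cyclic loess, 302 and 188 with median centring and 65 and 17 with normexp background correction. With the main scaling the counts were 148 and 116 for only features well above background on all 9 arrays, and 182 and 227 without a filter on dim features. Leaving out 1 array gave 149 to 199 higher and 108 to 519 lower. The highest was AT5G24640, at least 53.9-fold (adjusted p = 0.000123). AT3G42930, annotated as a pseudogene, rose by 4.90 ± 0.21 (adjusted p = 5.03e-05), AT4G12735 by 4.66 ± 0.18 (adjusted p = 3.01e-05) and AT2G41730 by 4.43 ± 0.18 (adjusted p = 3.70e-05). PRX52 was at least 2.02-fold higher (adjusted p = 0.000102). The non-coding RNA AT2G01422 changed by −6.31 ± 0.46 (adjusted p = 0.000650), the pseudogene AT5G34810 was at least 2.75-fold lower (adjusted p = 0.00167) and AT5G34830 at least 3.88-fold lower (adjusted p = 0.000440). AT3G28899 changed by −2.56 ± 0.26 (adjusted p = 0.00276), with 1 of 3 crwn1/4 arrays well above background. ARD3, an acireductone dioxygenase gene, was at least 1.39-fold lower (adjusted p = 0.0299).

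All 20 measured photosynthesis genes were higher in crwn1/4 than in Col-0, with a median of 0.42 (camera adjusted p = 1.22e-06, adjusted p = 0.725 with an estimated correlation, fry adjusted p = 0.0664). Of these 6 rose, 0 fell and 14 did not pass, and 10 rose when adjusted over the list alone. Examples are PSBO1 of photosystem II (0.56 ± 0.10, adjusted p = 0.0186) and LHCB4.1, an antenna gene (0.66 ± 0.13, adjusted p = 0.0274). Of 15 genes chosen as further markers of shoot epidermis and leaf, 8 were measured. Their median was −0.26 ± 0.17 (SE over the 8 genes, taken as independent), with ATML1 at −0.61 ± 0.15 (SE from the arrays, limma adjusted p = 0.0462). Abscisic acid and water stress genes had a median of 0.25 (camera adjusted p = 0.000428, and adjusted p = 0.404 with an estimated correlation). Of 13 members 3 rose, 0 fell and 10 did not pass, and 4 rose when adjusted over the list alone, with the dehydrin gene LTI30 at 0.76 ± 0.07 (adjusted p = 0.00176) after COR47. Low oxygen genes had a median of 0.23 (camera adjusted p = 0.00325, and adjusted p = 0.404 with an estimated correlation). Of 10 members 3 rose, 0 fell and 7 did not pass, with 4 higher when adjusted over the list alone. Besides PDC1 these were LBD41 (0.46 ± 0.08, adjusted p = 0.0207) and PCO1 (AT5G15120), a plant cysteine oxidase gene (0.36 ± 0.07, adjusted p = 0.0243).

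Endodermis and suberin markers had a median of 0.13 (camera adjusted p = 0.00197, adjusted p = 0.725 with an estimated correlation, fry adjusted p = 0.0664). Of 23 members 3 rose, 1 fell and 19 did not pass, and 8 rose and 2 fell when adjusted over the list alone. The suberin gene CYP86A1 rose by 0.54 ± 0.07 (adjusted p = 0.00645), while CASP5, a Casparian strip gene, fell by 0.63 ± 0.11 (adjusted p = 0.0208). The list's call held in 11 of 16 alternatives other than leave-outs and was lost with quantile normalization (median 0.07, adjusted p = 0.0706), normexp with quantile normalization (0.0604), the deposited value table (0.0943) and cyclic loess (median 0.07, adjusted p = 0.113), in a range of 0.00124 to 0.725. Copper homeostasis genes had a median of 0.13 (camera adjusted p = 0.00550, and adjusted p = 0.404 with an estimated correlation). Of 18 members 4 rose, 0 fell and 14 did not pass, with 6 higher when adjusted over the list alone. FRO4, a copper reductase gene, rose by 0.96 ± 0.11 (adjusted p = 0.00476) and the metal transporter gene ZIP2 by 0.55 ± 0.09 (adjusted p = 0.0160).

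The other 18 lists did not pass in crwn1/4, though 4 of them did so in a few of 16 alternatives other than leave-outs. These were core histones in 3 (adjusted p of 0.0246 to 0.973 over the 16), xylem markers in 3 (0.0318 to 0.793), salicylic acid in 2 (0.0177 to 0.725) and DNA methylation in 1 (0.0369 to 0.793). Without Col-0 replicate 1, 6 of the 18 passed: salicylic acid, DNA replication and root tip (adjusted p = 0.0462 each), mitotic (0.0481), DNA methylation (0.00137) and xylem (0.0145). Without Col-0 replicate 2 salicylic acid (0.0254) and phosphate starvation (0.0363) passed, and without Col-0 replicate 3 root hair markers (0.0345). In the DNA damage response list 4 rose, 1 fell and 18 did not pass of 23, also when adjusted over the list alone (camera adjusted p = 0.368). Its median was −0.04 and its mean 0.12, and the median lay above 0 with quantile normalization, median centring, cyclic loess or the deposited value table. SMR7 rose by 0.91 ± 0.11 (adjusted p = 0.00471), and WEE1, a kinase gene that delays division, fell by 0.41 ± 0.08 (adjusted p = 0.0314). Of 24 salicylic acid and immunity genes 4 rose and 1 fell (camera adjusted p = 0.1002). AZI1 rose by 1.97 ± 0.10 (adjusted p = 0.000138) and WRKY46 by 1.35 ± 0.12 (adjusted p = 0.00158). CBP60G, an activator of salicylic acid synthesis, fell by 1.41 ± 0.19 (adjusted p = 0.00738). Heat shock genes numbered 2 rising and 4 falling of 15 (camera adjusted p = 0.396). The heat shock factor gene HSFA2 changed by 0.88 ± 0.12 (adjusted p = 0.00746) and the chaperone genes HSP90.1 and HOP3 by −0.82 ± 0.11 and −0.76 ± 0.07 (adjusted p = 0.00886 and 0.00190). Of 14 flavonoid genes 3 rose and 1 fell (camera adjusted p = 0.443), with CHI (TT5) at 0.63 ± 0.09 (adjusted p = 0.00927). Of 22 iron deficiency genes 2 rose and 3 fell (camera adjusted p = 0.348). The nicotianamine synthase gene NAS2 changed by 1.09 ± 0.09 (adjusted p = 0.00112) and the iron signalling peptide gene IMA2 (AT1G47395) by −1.23 ± 0.18 (adjusted p = 0.0119). Jasmonate and boron lists had 1 rising and 1 falling each, of 16 and 6 (camera adjusted p = 0.441 and 0.683), and phosphate starvation 2 rising and 1 falling of 17 (camera adjusted p = 0.1002). Of the 19 nuclear lamina genes CRWN1 and CRWN4 fell and 17 did not pass (camera adjusted p = 0.716), which gave the list a mean of −0.73 beside a median of 0.00. By fry it passed (adjusted p = 0.000229), and without these 2 genes it did not (adjusted p = 0.499). Root hair and root tip markers had 0 rising and 1 falling each (camera adjusted p = 0.523 and 0.119). In the condensin, mitotic, DNA replication, core histone, DNA methylation, clock and xylem lists 0 members passed (camera adjusted p = 0.441, 0.716, 0.444, 0.368, 0.119, 0.808 and 0.119).

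Of the 3 crwn1/4 arrays, replicate 3 lay alone on slide 2 (scan 2), and the other 8 arrays shared slide 1. With the slide as a block, which compares the groups within slide 1, 866 features were called in crwn1/4. The medians of the 5 lists were 0.42 for photosynthesis, 0.29 for abscisic acid, 0.28 for low oxygen, 0.11 for endodermis and 0.09 for copper (adjusted p = 9.06e-06, 0.00227, 0.00161, 0.00775 and 0.00775). Xylem markers then passed as well (−0.20, adjusted p = 0.0318). Of the 69 passing tests of named genes 25 no longer passed, among them ARD3, PSAF, PSBO1, LHCB4.1, LBD41, PCO1, CASP5 and WEE1. Over the alternatives other than leave-outs the lists' adjusted p ran from 1.53e-07 to 0.725 for photosynthesis, 7.35e-05 to 0.404 for abscisic acid and 0.00148 to 0.404 for low oxygen. It ran from 0.00124 to 0.725 for endodermis, 0.00349 to 0.404 for copper and 0.0318 to 0.793 for xylem. Of the 69 tests 42 held in each of the 9 fits with 1 array left out, all of them with an adjusted p of 0.0160 or less, and the 27 lost in at least 1 had 0.0156 or more. The count of 3156 fell to 926 and 866 without crwn1/4 replicates 2 and 3 and to 1992 and 1386 without Col-0 replicates 1 and 3. It fell to 1766, 1815 and 1926 without cap-h2-2 replicates 1, 2 and 3, and with median centring 2193 features were higher and 836 lower.

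The direct comparison of crwn1/4 with cap-h2-2 tests where the mutants differ from each other. Higher in crwn1/4 were the water stress genes COR47 by 2.24 ± 0.08 (SE, n = 3; limma adjusted p = 2.74e-05), KIN1 by 1.31 ± 0.10 (adjusted p = 0.000564) and LTI30 by 1.18 ± 0.07 (adjusted p = 0.000259). PDC1 was higher by 1.70 ± 0.13 (adjusted p = 0.000841) and CHI (TT5) by 1.26 ± 0.09 (adjusted p = 0.000508). Lower in crwn1/4 were HSP90.1 by −1.31 ± 0.11 (adjusted p = 0.00127), HOP3 by −1.05 ± 0.07 (adjusted p = 0.000465) and SMR7 by −1.10 ± 0.11 (adjusted p = 0.00221). In all, 1300 features differed, 684 higher and 616 lower in crwn1/4. An unadjusted p under 0.05 was found for 6559 features.

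Among single genes, the pseudogene AT3G42930 was at least 36.1-fold higher in crwn1/4 than in cap-h2-2 (adjusted p = 2.74e-05), AT5G24640 was higher by 4.22 ± 0.32 (adjusted p = 0.000745) and AT4G12735 by 4.03 ± 0.18 (adjusted p = 7.03e-05). DIR1, a lipid transfer protein gene of systemic acquired resistance, differed by 5.28 ± 0.80 (adjusted p = 0.0146, 1 of 3 cap-h2-2 arrays well above background), and by 2.94 with normexp background correction. The defensin gene PDF1.4 was at least 6.87-fold lower (adjusted p = 0.00921), AGL95 at least 2.64-fold lower (adjusted p = 0.000244) and LBD26 lower by −2.78 ± 0.09 (adjusted p = 1.84e-05). The genes named after the lines differed as well, CAP-H2 at least 4.12-fold higher and CRWN1 at least 131-fold lower in crwn1/4 (adjusted p = 6.06e-05 and 6.44e-09). CRWN4 stood at −4.58 ± 0.34 (1 of 3 crwn1/4 arrays well above background) and ATBCAT-5 at least 14.3-fold lower (adjusted p = 0.000662 and 7.13e-07).

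Higher in crwn1/4 than in cap-h2-2 as a list were photosynthesis genes, with a median of 0.52 and 3 of 20 higher, 0 lower and 17 not passing, or 17 higher when adjusted over the list alone (camera adjusted p = 8.61e-11, and adjusted p = 0.247 with an estimated correlation). LHCB1.2 (CAB3) was higher by 2.71 ± 0.47 (adjusted p = 0.0225). Abscisic acid genes had a median of 0.52 with 5 of 13 higher, 0 lower and 8 not passing, or 6 higher when adjusted over the list alone (camera adjusted p = 1.42e-07, and adjusted p = 0.141 with an estimated correlation). Flavonoid genes had a median of 0.37 with 5 of 14 higher, 0 lower and 9 not passing, or 8 higher when adjusted over the list alone (camera adjusted p = 1.42e-05, and adjusted p = 0.141 with an estimated correlation), F3H at 0.81 ± 0.09 (adjusted p = 0.00398). Low oxygen genes had a median of 0.29 with 4 of 10 higher, 0 lower and 6 not passing, or 6 higher when adjusted over the list alone (camera adjusted p = 0.000188, and adjusted p = 0.141 with an estimated correlation). Endodermis and suberin markers had a median of 0.20 with 6 of 23 higher, 0 lower and 17 not passing, or 10 higher when adjusted over the list alone (camera adjusted p = 0.000306, and adjusted p = 0.509 with an estimated correlation), among them the suberin transporter gene ABCG2 at 0.58 ± 0.09 (adjusted p = 0.0127). Copper genes had a median of 0.13 with FRO4 (0.85 ± 0.11, adjusted p = 0.00896) higher and 17 not passing, or 3 higher when adjusted over the list alone (camera adjusted p = 0.0124, and adjusted p = 0.141 with an estimated correlation).

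Lower in crwn1/4 than in cap-h2-2 were heat shock genes, with a median of −0.42, 1 higher, 5 lower and 9 not passing of 15, or 2 higher and 8 lower when adjusted over the list alone (camera adjusted p = 9.85e-06, and adjusted p = 0.141 with an estimated correlation). HSFA2 was the 1 higher, by 0.57 ± 0.12 (adjusted p = 0.0409). DNA damage response genes had a median of −0.23, 1 higher, 5 lower and 17 not passing of 23, or 1 higher and 9 lower when adjusted over the list alone (camera adjusted p = 8.37e-06, and adjusted p = 0.141 with an estimated correlation). NAC044 was the 1 higher, by 0.54 ± 0.07 (adjusted p = 0.0104), and XRI1, a gene induced by X-rays, was lower by −0.49 ± 0.06 (adjusted p = 0.00711). Xylem markers had a median of −0.28 with 0 of 11 passing, or 7 lower when adjusted over the list alone (camera adjusted p = 1.14e-05, and adjusted p = 0.201 with an estimated correlation). Jasmonate genes had a median of −0.18 with 1 of 16 lower, JAZ5 by −0.81 ± 0.09 (adjusted p = 0.00334), also when adjusted over the list alone (camera adjusted p = 0.0334, and adjusted p = 0.141 with an estimated correlation). The mitotic list passed with a median of 0.06 and 1 of 27 higher (camera adjusted p = 0.0450, and adjusted p = 0.703 with an estimated correlation), the core histone list with 0.16 and 0 of 13 passing (camera adjusted p = 0.0450, and adjusted p = 0.547 with an estimated correlation). By fry the mitotic and core histone lists did not pass (adjusted p = 0.386 and 0.0741). Of 16 alternatives other than leave-outs the jasmonate, mitotic and core histone calls held in 12, 11 and 9. The jasmonate call was lost with normexp background correction (adjusted p = 0.0772), normexp with quantile normalization (0.0621) and the deposited value table (0.0757), in a range of 0.0153 to 0.141. The mitotic call was lost with median centring (adjusted p = 0.120), normexp with quantile normalization (0.0883), the value table (0.0879) and the replicate block (0.0534), in a range of 0.00148 to 0.703. The core histone call was lost with quantile normalization (adjusted p = 0.0505), median centring (0.115), normexp with quantile normalization (0.0921), the value table (0.0976), only the 6 arrays compared (0.0518) and the replicate block (0.0534), in a range of 0.0190 to 0.547. The jasmonate, mitotic and core histone calls were each lost without Col-0 replicate 3 (adjusted p = 0.0650, 0.0650 and 0.0722), cap-h2-2 replicate 2 (0.0902, 0.171 and 0.138) and crwn1/4 replicate 2 (0.0726, 0.451 and 0.199). The mitotic call was lost also without crwn1/4 replicate 1 (0.0567) and the core histone call without cap-h2-2 replicate 1 (0.0723). Of the lists that did not pass, iron deficiency had 2 of 22 higher and 1 lower (camera adjusted p = 0.672), with S8H at 2.37 ± 0.28 (adjusted p = 0.00580). Salicylic acid and immunity had 2 of 24 higher, 0 lower (camera adjusted p = 0.490), and the remaining 9 lists had camera adjusted p of 0.0885 to 0.950. By fry the condensin and nuclear lamina lists passed (adjusted p = 0.0271 and 0.000122), and without the genes the lines are named after neither did (adjusted p = 0.734 each). Of the 16 alternatives other than leave-outs, the condensin list passed camera with the slide block (adjusted p = 0.0309, in a range of 0.0309 to 0.686). DNA methylation did so with only the 6 arrays compared (0.0479, in a range of 0.0479 to 0.703). Condensin passed also without cap-h2-2 replicate 3 (0.0474) and crwn1/4 replicate 3 (0.0309). DNA methylation passed also without Col-0 replicate 1 (0.0397), cap-h2-2 replicate 2 (0.0303) and crwn1/4 replicate 1 (0.0444). Root tip markers passed without cap-h2-2 replicate 2 (0.0305).

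With the slide as a block 734 features differed between the mutants, and the medians were 0.48 for photosynthesis, 0.30 for abscisic acid, 0.29 for flavonoid, 0.37 for low oxygen and −0.50 for heat shock genes. The count of 1300 became 430, 536 and 412 without cap-h2-2 replicates 1, 2 and 3 and 509, 443 and 734 without crwn1/4 replicates 1, 2 and 3. Of the 46 passing tests of named genes the 24 with an adjusted p of 0.0111 or less held in each fit with 1 array left out. With the slide as a block 15 of the 46 no longer passed.

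**Figure D3:**
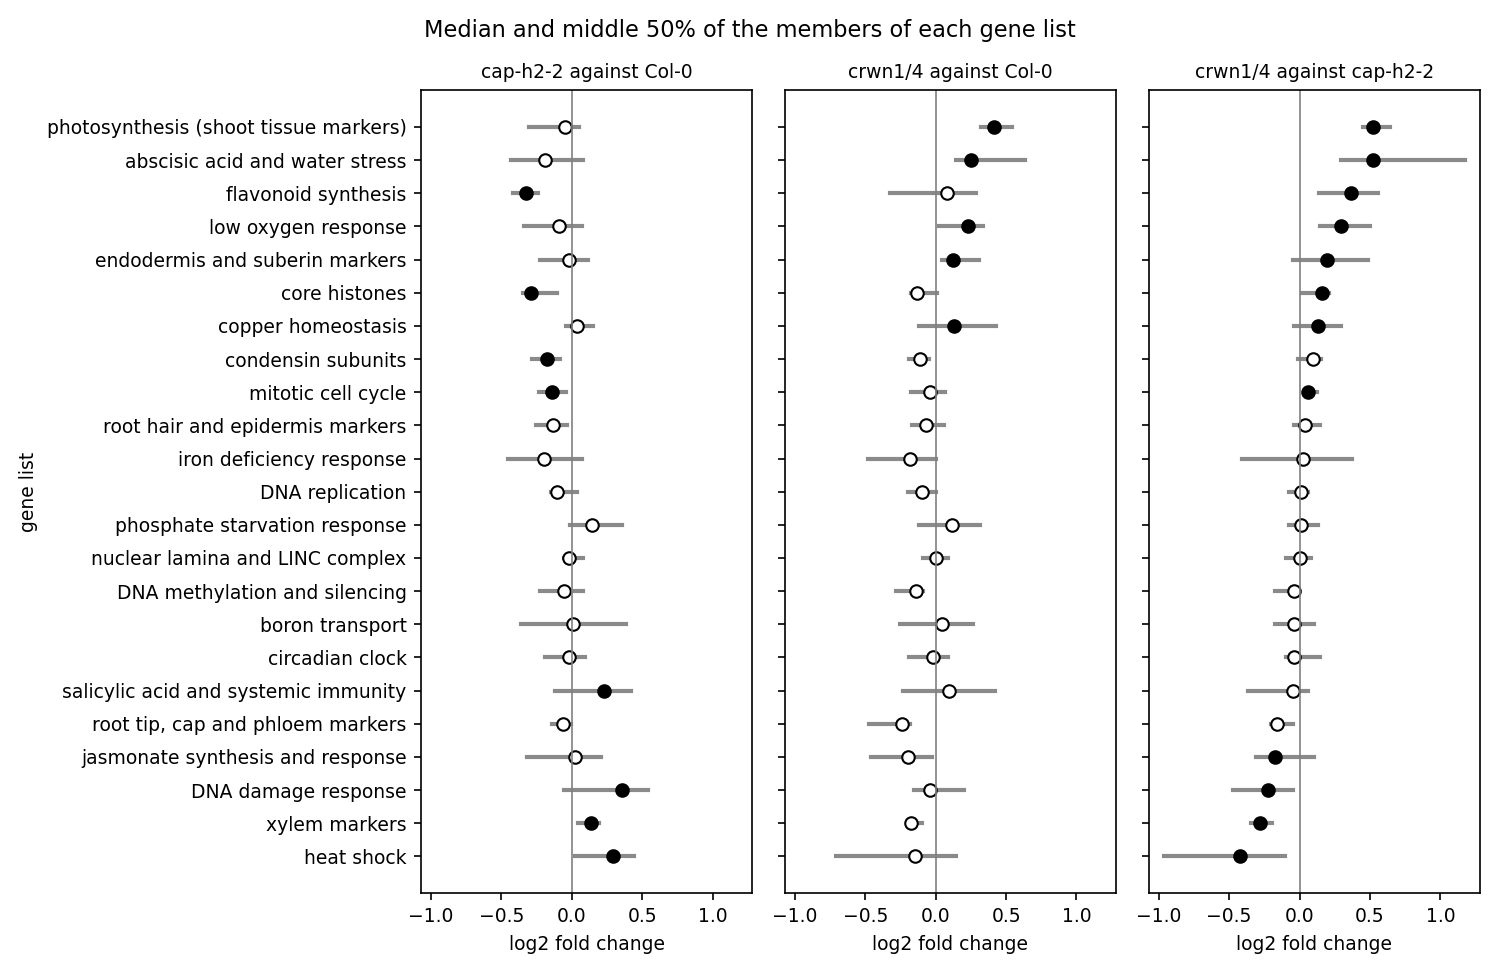
Median log2 fold change (points) and the middle 50% of members (grey lines) of the 23 gene lists (vertical axis) in cap-h2-2 and crwn1/4 against Col-0 and in crwn1/4 against cap-h2-2. Filled points passed camera with the preset correlation. Photosynthesis genes stood at 0.42 in crwn1/4 against Col-0 and DNA damage response genes at 0.36 in cap-h2-2 against Col-0.

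Many features changed alike in both mutants. PRX52, RTFL1 and ERF71 were higher in both and the non-coding RNA AT2G01422 was lower in both. AT2G18193, named after its values were seen, rose by 2.19 ± 0.12 in cap-h2-2 and 2.04 ± 0.12 in crwn1/4 (adjusted p = 0.000472 and 0.000261). In all, 521 features rose in both and 408 fell in both, 929 together, where lists of the same sizes drawn independently would share 60.2 and 44.2. The 100 simulated pairs of unchanged groups set against the same 3 Col-0 arrays gave at most 1, but unchanged genes are rarely called at all, so this value does not measure how far shared arrays raise the overlap of genes that changed. Another 61 features went opposite ways, 26 higher in cap-h2-2 and lower in crwn1/4 and 35 the reverse, where independent lists would share 54.9 and 48.5. Over all features the fold changes of both mutants had a covariance of 0.101, against a simulated median of 0.0197 from the shared Col-0 arrays alone, a difference of 0.0809. Their correlation was 0.63 against a simulated 0.50. The 3 Col-0 arrays cannot be split into sets of 2 or more, so part of the overlap may come from these shared arrays. With the slide as a block 352 features were called alike, and without 1 array at a time the number was 622 and 642 for Col-0 replicates 1 and 2, 395 for Col-0 replicate 3, 215, 243 and 246 for the cap-h2-2 replicates and 540, 374 and 352 for the crwn1/4 replicates.

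**Figure D4:**
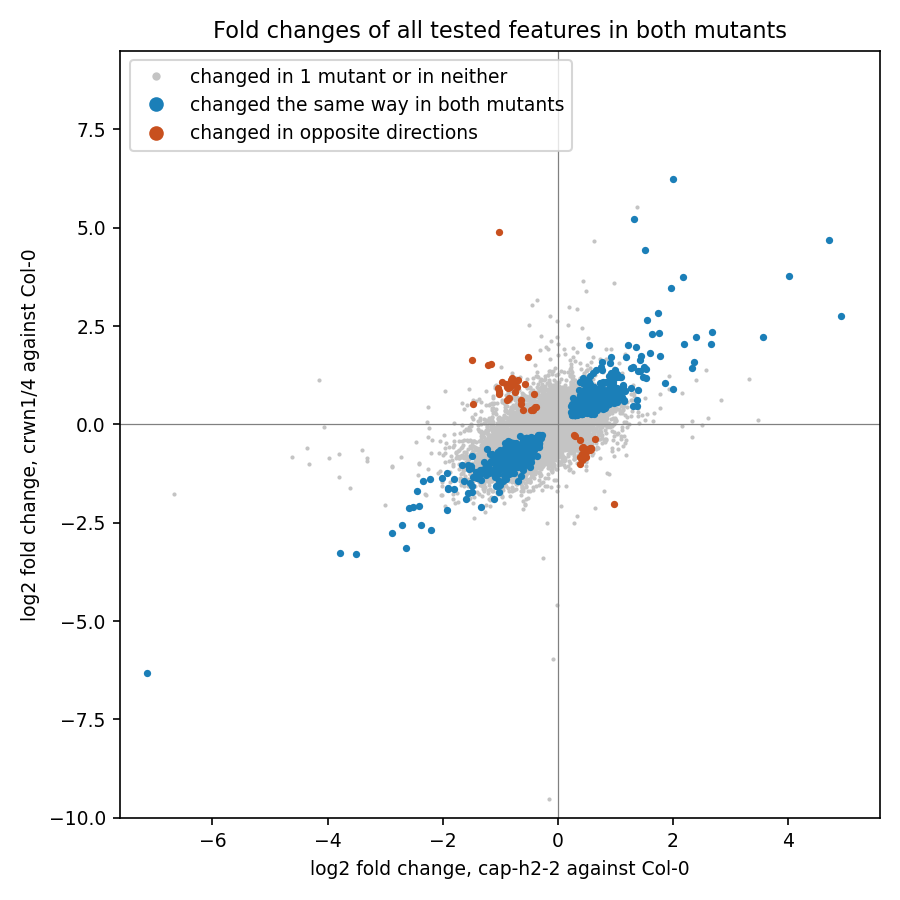
Log2 fold change of each of the 36420 tested features in cap-h2-2 (horizontal axis) and crwn1/4 (vertical axis), each against the same 3 Col-0 arrays. Blue points (929) had an adjusted p under 0.05 in both with the same direction, orange points (61) in both with opposite directions, and grey points are all others.

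Genes annotated as pseudogenes, the class that holds the transposable element genes of the array, made up 6.64% of the 24272 tested loci with an annotation. They were 15.1% of the loci that fell in cap-h2-2 (97 of 644, odds ratio 2.59, Fisher's exact test, two-sided, adjusted p = 4.70e-14) and 15.3% of those that fell in crwn1/4 (128 of 834, odds ratio 2.68, adjusted p = 9.35e-19). They were 1.45% of the loci that rose in cap-h2-2 (17 of 1173, odds ratio 0.198, adjusted p = 1.28e-17) and 0.912% of those that rose in crwn1/4 (13 of 1425, odds ratio 0.122, adjusted p = 6.21e-27). Between the mutants they were fewer among the higher (odds ratio 0.475) and among the lower loci (odds ratio 0.453, both adjusted p = 0.00119). Dim features as a whole read lower in the mutants, and the dimmest 7284 features had a median of −0.42 in cap-h2-2 and −0.33 in crwn1/4. With quantile normalization the odds ratio among loci that fell in cap-h2-2 was 1.16 and no longer passed, and without a filter on dim features that in crwn1/4 turned to 0.813.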

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

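Tests chosen only after the result was seen were those of dividing cells and of the Col-0 group's plants or RNA; the test of the row on the slide was added after that of the place was known. In all 61 features fell in one mutant and rose in the other. Single genes of flavonoid synthesis and water stress were among them: TT5 (CHI), the chalcone isomerase gene, differed by 1.26 and F3H by 0.81 in the direct test of crwn1/4 against cap-h2-2 (limma, 3 arrays per group), and the dehydrin genes LTI30 and ERD10 by 1.18 and 0.82, all higher in crwn1/4. The chaperone gene HSP90.1 differed by −1.31, and the pseudogene AT3G42930 by 5.92. Among lists, photosynthesis genes differed by a median of 0.52, abscisic acid genes by 0.52, flavonoid genes by 0.37, low oxygen genes by 0.29 and endodermis and suberin markers by 0.20. Heat shock genes differed by −0.42, xylem markers by −0.28 and DNA damage response genes by −0.23. None of these lists passed with an estimated correlation (adjusted p = 0.247, 0.141, 0.141, 0.141 and 0.509 for the former 5 and 0.141, 0.201 and 0.141 for the latter 3), and with the slide as a block the abscisic acid median was 0.30.

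DNA damage response genes such as SMR7 and NAC044 were higher in cap-h2-2. More dividing cells in the sampled roots would raise mitotic genes as well. Their median was −0.14 ± 0.032, and 4 of 27 were higher, so mitotic genes showed no rise at this scaling. The SE is over genes taken as independent, though they varied together (estimated correlation 0.505). With median centring the median was 0.02, and the mitotic list did not pass by fry (adjusted p = 0.229). SMR7, SMR5 and NAC044 themselves act to restrain division, so mitotic transcripts cannot measure the share of dividing cells here. The question stays open. Cyclic loess normalization argues against a trend with brightness. Under it the DNA damage list passed with a median of 0.44 (camera adjusted p = 7.92e-06, in a range of 2.14e-06 to 0.570 over the alternatives other than leave-outs). The list did not pass with an estimated correlation (adjusted p = 0.570).

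The fold changes of both mutants went the same way in many genes, PRX52 and ERF71 among them. The covariance was 0.101, above the highest of 100 simulated unchanged groups that shared the Col-0 arrays (0.0215), and with cyclic loess normalization it was 0.0808 against 0.0194, so chance values of the shared arrays and a brightness trend are argued against as the whole cause. Of 352 genes called alike without crwn1/4 replicate 3, which lay on the other slide at the place of a Col-0 array, 100% were on the mutants' side in that array. Of 55 called alike without the 2 mutant arrays in the row of Col-0, 100% were so in both. For these 352 and 55 genes this argues against the place and the row, provided that a place acts alike on both slides. The rest of the 929 features called alike were not covered. It stays open whether plants or RNA of the Col-0 group differed from both mutants for another reason, since Col-0 is the only control and the first principal component, which parts it from both mutants, holds 34.5% of the variance.

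Photosynthesis genes such as PSAF and PSBO1 were higher in crwn1/4. Shoot tissue carried into the samples would raise other shoot genes that are low in roots. The 8 measured markers had a median of −0.26 ± 0.17 against 0.42 ± 0.057 for the list (SE over genes, taken as independent). A marker median plus SE below the list's median had been named in advance as arguing against shoot tissue. The markers cannot decide it. PDF1 and KCS10 had log2 levels of 2.28 and −0.03, so a trace of shoot tissue may not move them, and changed by 0.00 and −0.08. YAB3, KCS6 (CER6), TGG1 and TGG2 lay near the lowest measured levels, where features as a whole read lower in crwn1/4. CER1 and ATML1 changed by 0.09 and −0.61, too few genes to settle it, so shoot tissue stays open. With cyclic loess normalization the photosynthesis list passed with a median of 0.41, which argues against a brightness trend (camera adjusted p = 7.85e-05, in a range of 1.53e-07 to 0.725 over the alternatives other than leave-outs). The list did not pass with an estimated correlation (adjusted p = 0.725) or by fry (adjusted p = 0.0664). A change in the plastids of the roots was not tested.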

How the results depend on the processing

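Cyclic loess, array weights, locus-named probes and the lists without the lines' own genes were chosen after seeing the data. CAP-H2, CRWN1 and CRWN4 kept direction and call under each alternative that measured them. Apart from leave-outs, mitotic genes in cap-h2-2, a list called, changed the sign of their median (0.02 with median centring), and medians of lists not called, such as DNA damage response and flavonoid synthesis in crwn1/4, did so too. Over the alternatives other than leave-outs, 2789 results of named genes stayed on their side of the threshold, 343 were lost and 56 gained, and for lists 1026, 60 and 18; where a cause is not given below, the cause was not tested.

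Without a filter on dim features, which tests more features, 795 (cap-h2-2), 1170 (crwn1/4) and 651 (between the mutants) were called and 278 alike. With the 6 arrays compared alone 1069 (cap-h2-2), 734 (crwn1/4) and 1421 (between the mutants) were called and 182 alike, so fewer arrays did not lower every count. The replicate block gave 401, 923 and 359, with 166 alike. Replicate numbers gave correlations of −0.19 to 0.08 in 9 pairs of the same number and −0.21 to 0.18 in 18 of different numbers. These values show no sign of a pairing by number, but 9 pairs cannot exclude a shared batch, and the labels do not say. The slide block, which sets aside crwn1/4 replicate 3, gave 866 in crwn1/4, 734 between the mutants and 352 alike. The trend with a robust prior gave 4166, 5296 and 2221, with 1868 alike, and the fold threshold, by its construction, 373, 481 and 292, with 100 alike. Median centring, which shifted all fold changes by 0.16 and 0.14 in the mutants against Col-0, gave 636 between the mutants and 4 lists in cap-h2-2, array weights gave 2192 between the mutants, and camera with an estimated correlation gave 0 lists in cap-h2-2, 0 in crwn1/4 and 0 between the mutants.

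The odds ratio of pseudogenes among loci that fell in cap-h2-2 was 1.155 with quantile normalization, 1.08 with normexp and quantile normalization, 1.299 with the value table and 1.15 with cyclic loess. Among loci that fell in crwn1/4 it reversed to 0.813 without a filter. Between the mutants it was 0.634 (higher) and 0.621 (lower) with median centring and 0.774 and 0.416 with the replicate block. With the fold threshold it was 0.473 among loci higher in cap-h2-2, 0.527 among those higher in crwn1/4, and between the mutants reversed to 1.08 (higher) and was 0.691 (lower).

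Without CAP-H2, which was the larger part of the condensin list's mean in cap-h2-2, that list no longer passed (adjusted p = 0.285). Leaving out 1 array gave 478 to 1970 calls in cap-h2-2, 866 to 2846 in crwn1/4 and 412 to 1834 between the mutants, 215 to 642 alike, and 5 to 8 lists called in cap-h2-2 and 5 to 11 in crwn1/4. Signal over background limits the dim genes: with normexp CAP-H2 changed by −1.02 in cap-h2-2 and CRWN1 by −5.43 in crwn1/4. The comparison by distance to the centromere and its window of 5 Mb were not run.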

Other observations

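The gene families, the neighbour order measure and the brightness comparison were chosen after the data had been seen. Enzymes that attach glutathione or sugars were higher in crwn1/4: of 25 measured GSTU genes, tau class glutathione transferases, 9 rose and 1 fell, with GSTU25 at 1.03 ± 0.10 (limma adjusted p = 0.00238) and GSTU24 at 0.94 ± 0.09 (adjusted p = 0.00200). Of 46 UGT genes, which encode glycosyltransferases, 10 rose and 1 fell, with UGT74E2 at 1.37 ± 0.18 (adjusted p = 0.00660) and UGT73B4 at 1.22 ± 0.13 (adjusted p = 0.00309). The medians were 0.27 and 0.15 (camera adjusted p = 0.000131 and 0.000863 over 148 families, and adjusted p = 0.450 and 0.399 with an estimated correlation). In cap-h2-2 the GSTU median was 0.02 and changed sign under 2 of 6 scalings, and the UGT median of 0.01 under 1. Autophagy genes of the ATG family were higher in both mutants, with 3 of 19 rising in cap-h2-2 and 5 in crwn1/4, 0 falling, and medians of 0.24 and 0.26 (camera adjusted p = 0.000122 and 9.06e-06, and adjusted p = 0.608 and 0.399 with an estimated correlation). ATG8B rose by 0.45 ± 0.07 and 0.38 ± 0.07 (adjusted p = 0.0152 and 0.0207). Both comparisons use the same 3 Col-0 arrays, so they are not independent. Between the mutants the ATG median was 0.05. Of 61 WRKY transcription factor genes 12 rose and 1 fell in cap-h2-2 and 14 rose and 1 fell in crwn1/4, with WRKY50 at 1.31 ± 0.10 in cap-h2-2 (adjusted p = 0.00169) and WRKY30 at 1.66 ± 0.25 in crwn1/4 (adjusted p = 0.0113). The WRKY medians were 0.10 and 0.15, and no list test is given for this family. Over all 24489 tested loci 1179 rose and 649 fell in cap-h2-2, and 1430 rose and 847 fell in crwn1/4. The same 3 Col-0 arrays served both comparisons here as well.

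SADHU3-2 and SADHU3-1, non-coding retroelements of the Sadhu family, fell by 1.48 ± 0.12 and 1.15 ± 0.12 in cap-h2-2 (adjusted p = 0.00227 and 0.00539) and rose by 1.65 ± 0.12 and 1.53 ± 0.12 in crwn1/4 (adjusted p = 0.000650 and 0.000976).

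Genes called in the same direction lay next to each other more often than in shuffled orders. In cap-h2-2 128 neighbouring pairs were alike, against a median of 73 in 10000 shuffles over 24068 genes, in crwn1/4 165 against 111, and between the mutants 48 against 20. In none of these comparisons did any shuffle reach the observed number. With cyclic loess normalization there were 89, 129 and 56 pairs against highest values of 75, 115 and 43. AZI1, EARLI1, AT4G12490 and AT4G12500 were higher in both mutants with medians of 1.50 and 2.32, 4 genes from AT5G34790 to AT5G34830 were lower in both with medians of −2.85 and −2.98, and 3 berberine bridge enzyme-like genes from AT1G26380 to AT1G26410 were lower in cap-h2-2 with a median of −3.40. Chance along the gene order is argued against, while tandem copies, shared regulation and probes that bind related genes stay open.

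Protein-coding genes in stretches rich in pseudogenes, with 50 neighbours on each side, stood in for genes near the centromere. With cyclic loess normalization and strata of brightness, the odds ratio of lying there among genes that fell was 1.01 in cap-h2-2 (95% interval 0.365 to 2.24, 6 of 385) and 0.900 in crwn1/4 (0.383 to 1.81, 8 of 548). An interval that includes 1 had been named in advance as arguing against more falling genes there, but with 6 and 8 such genes the intervals reach 2.24 and 1.81, so that bound was too loose and the question stays open.

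Dim features read lower in the mutants: of the dimmest 7284, 44 rose and 383 fell in cap-h2-2 and 72 rose and 411 fell in crwn1/4, while with cyclic loess normalization 119 rose and 116 fell and 187 rose and 172 fell. For 13 loci the array holds 243 pairs of probes of opposite strand; in the 80 pairs well above background on all arrays the fold changes correlated over pairs with r of 0.73 in cap-h2-2 and 0.80 in crwn1/4. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real splits called 2397, 3156 and 1300 features, each the 1 highest of its 10, and the highest other split 0, 0 and 1. Each other split mixes both genotypes in its groups, so a difference between genotypes widens the spread there and lowers the calls. The other splits therefore do not measure how many features unchanged samples would give.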
